A study of Mus musculus with 46 samples.

How the data were processed

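Total RNA from 46 snap-frozen livers of male mice in 10 groups was sequenced after library preparation with a NEBNext Ultra RNA kit, per the labels. The authors aligned the reads with STAR 2.7.8a to GRCm39 and counted them per gene with featureCounts 2.0, after quality control with FastQC 0.11.9 and MultiQC 1.10.1. The deposited tables hold raw counts per Ensembl gene, 1 column per library, without normalization, and a column of another unit, the summed exon length of each gene in bases, per the file headers. The release of the annotation and the counting strand are not stated. The values were checked to be whole numbers, and 46 columns in 4 tables were matched to the labels by their sample codes. The groups come from the labels. For the refed and Cav1 experiments the free text of the protocol gives a 12 h fast, while the sample characteristics give 10 h of fasting with 2 h of refeeding and 6 h of fasting, and the characteristics were used.

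Gene symbols were joined by Ensembl identifier from a mouse annotation on an earlier genome build. They cover 52083 of 55416 genes (94.0%), and genes without a symbol hold 0.764% of all counts. Coordinates are those of the deposited tables. Totals ranged from 6656342 to 23311539 counts per library. Reads amplified by PCR are not independent molecules, so floors and intervals drawn from counts cover counting error only. Among the refed livers, 14 genes that reach 1 CPM elsewhere have no count in any library, 12 of them mitochondrial and 2 on unplaced sequence. No pair among 85 pairs of libraries within groups was identical.

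Each comparison was tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr (minimum count 10, minimum total 15) and robust dispersions, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The Plvap effect on chow (fasted, and refed) and the Cav1 effect were fitted on their own table. The Plvap effects on western and high-fat diet, the diets against each other in controls, and the difference of the Plvap effect between diets were fitted on the 4 groups of the diet table. Differences of the Plvap effect between chow fasted livers and the other experiments, and refed, western and high-fat controls against chow fasted controls, were fitted on the 8 groups of the Plvap line joined by gene. The latter 3 span tables, so that table and condition cannot be separated. The mean Plvap effect over the 4 experiments uses the same joint fit and was added after the data were seen. CPM values are TMM-normalised. The targeted genes also had an exact two-sided permutation test on log2 CPM with a pseudocount of 0.5.

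Before the data were examined, 38 gene lists of metabolic pathways, hormone responses, liver zones, cell types, other tissues and technical classes were fixed, of which 37 had at least 2 tested members in some comparison. Each list was described by its called members, over all genes tested and adjusted over the list alone. Camera (limma 3.58.1) tested each list against the other genes with a preset correlation of 0.01 and with an estimated correlation. Fry tested whether the genes of a list move, on balance, one way. Adjustment was over the lists of 1 comparison. Folds against a group without counts are lower bounds against 3 counts over that group.

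Genes were named by a rule fixed at the same time. Per knockout comparison and for western against high-fat diet it took the targeted gene, then the 10 largest rises and 10 largest falls among called genes with at least 1 CPM in the higher group, a symbol other than a predicted gene and no overlap between the libraries of the groups. It then took up to 4 called members with the smallest p from each list with a camera call or at least 3 called members, and where fewer than 5 genes were called the 5 genes with the smallest p. Differences of effects and comparisons across tables used 5 genes each way without the overlap condition.

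Agreement between the 5 knockout comparisons was measured by Pearson and Spearman correlations of log2 fold changes across genes against 100 draws with permuted labels, and by Fisher's exact test of shared called genes, adjusted over the 10 pairs and over both directions. Called genes within 5 Mb of Plvap, Lrat and Cav1 were counted against all others with Fisher's exact test, with windows of 2 and 10 Mb as alternatives. Principal components used the 1000 most variable genes, and values that stand apart within a group were found with Dixon's test. Called genes that lie side by side were counted against 10000 permutations of the calls.

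Alternatives were DESeq2 1.42.0 with its default filtering, its size factors in edgeR, no filter, a filter at 1 CPM, limma-voom with sample quality weights, the replicate letter as a block, only the compared groups, and each library left out in turn. Removal of trends with gene length or GC content, and fits without mitochondrial genes and genes at 0 in a whole table, were added after the data were seen. GC content was computed from the same earlier genome build. Each count was also set against up to 100 other splits of its libraries into groups of the same sizes. The fits were tested on simulated data with 200 changed genes and the group sizes of the study: a 2-fold change was recovered for 77.6% of genes in the chow fasted Plvap comparison, 70.1% in the refed, 73.1% in the Cav1, 65.7% in the western and 62.7% in the high-fat one, with at most 7.69% false calls. Simulated counts were drawn independently for each gene and library, without structure shared between genes, so these shares may be too favourable for the real livers. Nothing in the deposited tables was left out of the fits other than by the filter.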

Results

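Bulk RNA sequencing was done on 46 livers of male mice in 10 groups, deposited as 4 tables of raw read counts over 55416 Ensembl genes. Plvap encodes a protein of the diaphragms that span caveolae and endothelial fenestrae. Its knockout was driven by Lrat-Cre, which is active in hepatic stellate cells, the vitamin A storing pericytes of the liver. Littermates were the controls. On chow after a 12 h fast there were 6 control and 5 knockout livers. After a 10 h fast with 2 h of refeeding there were 4 control and 4 knockout livers. After 6 weeks of western diet with fructose in the water there were 5 control and 4 knockout livers, and after 6 weeks of high-fat diet 5 of each, all fasted for 12 h. A further experiment compared 4 livers of whole-body Cav1 knockouts with 4 of C57BL/6N wild types after a 6 h fast. Cav1 encodes the main coat protein of caveolae. Libraries held from 6656342 counts (replicate D of the high-fat controls) to 23311539 (replicate B of the refed controls). Expression is given as CPM (library counts scaled by TMM), mean ± SD, and log2 fold changes ± SE are knockout against control unless said otherwise. Adjusted p values without another name are from edgeR.

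The first question was whether the targeted genes were lower where the labels place the knockout. Plvap (ENSMUSG00000034845, GRCm39 chromosome 8, 71950409 to 71964396) stood at 5.34 ± 0.958 CPM in chow fasted knockouts (n = 5) against 26.8 ± 4.42 in controls (n = 6), which is 19.9% of control. It was at 17.8% of control after refeeding (5.76 ± 0.961 against 32.3 ± 12.3 CPM, n = 4 and 4). On western diet it was at 18.8% (5.55 ± 0.562 against 29.5 ± 7.25 CPM, n = 4 and 5) and on high-fat diet at 25.3% (7.28 ± 2.61 against 28.7 ± 3.63 CPM, n = 5 and 5). The exact two-sided permutation p was 0.00216, 0.0286, 0.00794 and 0.00794 in that order, each the smallest its design allows. The edgeR adjusted p was 1.33e-07, 0.0327, 5.08e-06 and 2.72e-05. Cav1 (ENSMUSG00000007655, chromosome 6, 17306334 to 17341451) stood at 0.855 ± 0.55 CPM in Cav1 knockouts against 5.12 ± 1.03 in wild types (n = 4 and 4), or 16.7%, with adjusted p 0.0015 and exact permutation p 0.0286. Plvap itself was at 97.2% of wild type in the Cav1 knockouts (adjusted p 0.894). Cav1 did not pass the test in any Plvap experiment, with log2 fold changes of -0.47 ± 0.23 (chow fasted), -0.52 ± 0.29 (refed), 0.44 ± 0.33 (western) and -0.83 ± 0.31 (high-fat).

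**Figure D1:**
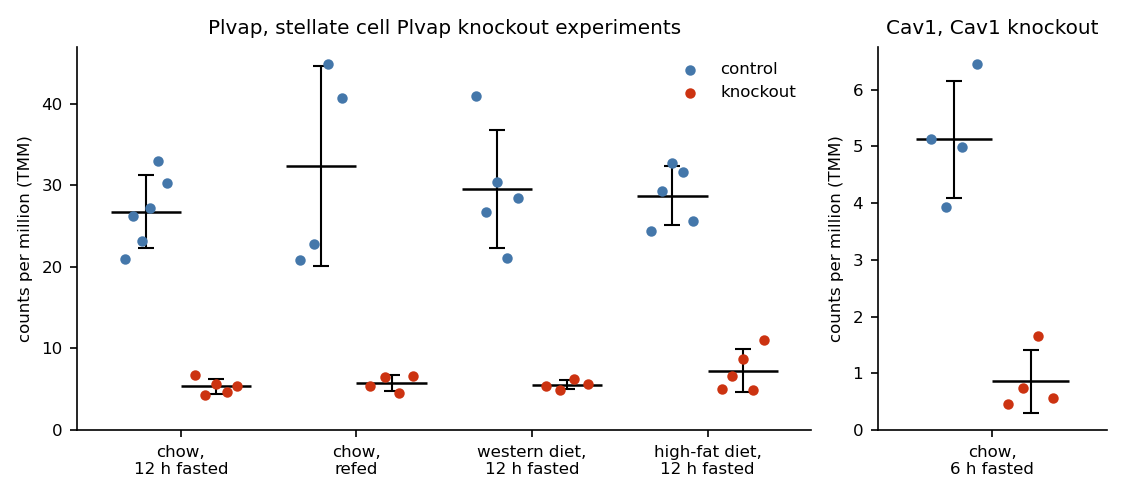
Normalised CPM of Plvap in the 4 Plvap experiments and of Cav1 in the Cav1 experiment, with 1 point per liver (blue control, red knockout), a line at each group mean and error bars of 1 SD. Mean Plvap in the knockouts was 17.8% to 25.3% of that in the controls, and Cav1 was at 16.7% of wild type.

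In chow fasted livers with the stellate cell knockout of Plvap, 7 of 27 PPARA targets that respond to fasting fell and none rose, and of 31 fatty acid oxidation genes 7 fell and 1 rose. Both lists were called as lower by camera with its preset correlation and not with an estimated one (adjusted p 0.242 for each). Cyp4a14, a fatty acid omega-hydroxylase and classical PPARA target, fell from 6451 ± 964 to 2610 ± 1020 CPM (-1.31 ± 0.22, adjusted p 0.0102). The peroxisomal enzyme Hsd17b4 fell by 0.48 ± 0.08, the mitochondrial reductase Decr1 by 0.55 ± 0.11 and the saturase Retsat by 0.84 ± 0.18 on the log2 scale. The acyl-CoA thioesterase Acot2 fell as well (-1.33 ± 0.24), though its groups overlapped. Abcd2, a peroxisomal transporter of very long chain acyl-CoA, rose (29.8 ± 6.06 against 11.4 ± 2.58 CPM, adjusted p 0.000749).

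Lipid storage genes moved both ways in the same livers. Of 39 genes of fatty acid uptake and lipid droplets 3 fell and 2 rose. Among them Cidec, a lipid droplet fusion protein also on the PPARA list, fell from 10.4 ± 1.63 to 3.87 ± 1.45 CPM (adjusted p 0.00223). Fitm1, which buds droplets from the endoplasmic reticulum, fell from 14.6 ± 2.38 to 8.29 ± 1.09. Dgat2, which completes triglyceride synthesis, rose from 322 ± 18 to 436 ± 28.8 CPM, and Gpihbp1, the capillary anchor of lipoprotein lipase, rose by 0.48 ± 0.11. Of 7 ketogenesis genes 1 fell, the ketone body exporter Slc16a1 (-0.73 ± 0.13, adjusted p 0.0121).

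Of 24 genes of growth hormone action and male bias 5 fell and none rose, and the list did not pass with an estimated correlation (adjusted p 0.203). The male-specific hydroxylases Cyp4a12b and Cyp4a12a fell by 1.75 ± 0.23 and 1.60 ± 0.23, and the urinary protein genes Mup21 and Mup20 by 1.83 ± 0.26 and 0.68 ± 0.17. Of 10 female-biased genes 3 rose: Cyp3a44 (1.75 ± 0.38), Abcd2 and the prolactin receptor Prlr (0.64 ± 0.15). That list did not pass with an estimated correlation either (adjusted p 0.0759). Further genes changed by more than 2-fold. Tff3, a secreted trefoil peptide, rose from 18.1 ± 12.3 to 175 ± 59.2 CPM (adjusted p 0.0192). The hepcidin paralog Hamp2 rose from 2.25 ± 1.59 to 10.9 ± 3.03 CPM, the retinol dehydrogenase relative Rdh16f2 from 128 ± 26.4 to 301 ± 42.7, and the methyltransferase Inmt from 355 ± 55.9 to 825 ± 179. The axonal protein gene Cntnap1 fell from 5.64 ± 1.52 to 1.36 ± 0.55 CPM and the laminin chain Lamb3 from 9.95 ± 0.89 to 3.78 ± 1.87.

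Other cell types and quality measures gave these values in the chow fasted livers. Of 29 stellate cell genes 1 rose and 28 did not pass (camera adjusted p 0.798). None of 34 fibrogenesis genes passed (camera adjusted p 0.11), and of 32 endothelial genes 1 rose and 1 fell (0.279). Of 78 ribosomal protein genes 4 rose, among them Rpl13 (0.35 ± 0.08) and Rpl7a (0.31 ± 0.08), and none fell. Log2 fold changes fell with gene length across genes (Spearman -0.21), so that the short ribosomal protein genes lay on the side that rose. Alb, encoding albumin and named here after its values were seen, was at 195% of control (0.96 ± 0.12, adjusted p 0.000582). No Kupffer cell gene of 25 passed, while 1 of 16 lymphocyte and neutrophil genes rose (Igkc, 0.61 ± 0.15). Of 31 acute phase genes 2 rose (Hamp2 and the fibrinogen chain Fga), of 30 interferon genes 1 (Irf7, 0.54 ± 0.11), of 24 clock genes 2 (among them Tspan4), of 24 periportal genes 1 (Uroc1) and of 19 glucocorticoid genes 1 (Hsd11b1).

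In this comparison edgeR called 145 genes higher and 144 lower of 12840 at an adjusted p under 0.05. Camera with a preset correlation called 15 of 37 lists: PPARA targets (adjusted p 7.69e-14), oxidation (2.75e-13), ketogenesis (0.00415), growth hormone and male-biased (5.44e-07), lipid uptake and droplets (0.0114) and adipose tissue (0.0159) as lower, and ribosomal protein (1.92e-16), Kupffer cell (2.76e-06), female-biased (2.16e-05), glucocorticoid (6.49e-05), lymphocyte and neutrophil (6.49e-05), interferon (7.3e-05), acute phase (0.000229), periportal (0.00332) and clock (0.0129) as higher. With an estimated correlation none passed. The lowest adjusted p was then 0.0759 for female-biased genes, with 0.242 for PPARA targets and for oxidation, 0.203 for male-biased genes, 0.288 for ribosomal protein and 0.347 for Kupffer cell genes. Fry called 10 of the lists. Adjusted over the list alone, 17 PPARA targets fell and none rose, 22 oxidation genes fell and 1 rose, 9 male-biased genes fell, 5 female-biased genes rose and 30 ribosomal protein genes rose. EdgeR called 160, 134 or 101 genes without control A, B or C and 139, 97, 550, 133 or 90 without knockout A, B, C, D or E. DESeq2 called 713.

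Refeeding asked whether the knockout acts on the fed liver. Beside Plvap, 2 genes fell and none rose of 13228. Fitm1 (ENSMUSG00000022215, chromosome 14, 55813074 to 55814411) fell from 23.3 ± 3.06 to 7.98 ± 2.04 CPM (-1.55 ± 0.19, adjusted p 0.0328). Slc27a1, a plasma membrane fatty acid transporter (ENSMUSG00000031808, chromosome 8, 72021526 to 72039946), fell from 25.2 ± 4.16 to 11.7 ± 0.89 CPM (-1.11 ± 0.14, adjusted p 0.035). It lies 0.0571 Mb from Plvap and did not pass in chow fasted (-0.56 ± 0.17, adjusted p 0.0942) or western diet knockouts (-0.58 ± 0.17, adjusted p 0.321), and on high-fat diet it did not fall (0.21 ± 0.16, adjusted p 0.589). Clstn3 (8.71 ± 0.881 against 28.8 ± 10.7 CPM) and Rdh16f2 (174 ± 26 against 86.8 ± 13.8 CPM) had adjusted p 0.0656 and did not pass. With the replicate letter as a block both did, with adjusted p 0.027 for Clstn3 and 0.00882 for Rdh16f2. Alb, also named after its values were seen, was at 168% of control, with adjusted p 0.167.

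Camera with a preset correlation called 12 of 35 lists in the refed livers. Lower were fatty acid oxidation (adjusted p 7.19e-09, median -0.24), lipid uptake and droplets (2.5e-07, median -0.22), PPARA targets (2.58e-07, median -0.26), oxidative phosphorylation (3.67e-06), immediate early genes (0.00439) and antioxidant genes (0.00953). Higher were interferon (7.7e-11, median 0.42), cholesterol synthesis (6.84e-05, median 0.40), periportal (0.00189), female-biased (0.00189), unfolded protein response (0.00439) and Kupffer cell genes (0.0439). None passed with an estimated correlation (lowest adjusted p 0.235, for lipid uptake and droplets) or by fry. Adjusted over the list alone, 10 lipid uptake and droplet genes, 6 oxidation genes and 6 PPARA targets fell. Log2 fold changes rose with gene length in this experiment (Spearman 0.27). Controls and knockouts that share a replicate letter resembled each other here (correlations 0.208 to 0.329), and with the letter as a block edgeR called 30 genes, 14 of them higher. Without control B edgeR called 1 gene, and without control D, knockout A or knockout B it called 0. Plvap itself had adjusted p 0.0871 without control D and 0.122, 0.171, 0.0615 or 0.0833 without knockout A, B, C or D. DESeq2 called 59 genes, and 1024 had an unadjusted p under 0.05.

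On western diet the knockout changed 2 of 13533 genes, Plvap and Rdh16f2. Rdh16f2 (ENSMUSG00000074639, chromosome 10, 127702343 to 127713186) rose from 75.8 ± 24.2 to 170 ± 28.2 CPM (1.16 ± 0.19, adjusted p 0.0413). Cidec stood at 5.94 ± 1.18 against 22.9 ± 12.5 CPM but did not pass (adjusted p 0.114), nor did Mlxip (-0.81 ± 0.16) or Arhgap26 (0.88 ± 0.18), both at 0.163. Camera with a preset correlation called 10 of 37 lists. Ribosomal protein (adjusted p 5.57e-08), acute phase (0.0129), blood (0.0117), pancreas (0.0117) and mitochondrially encoded genes (0.0214) were higher. PPARA targets (3.08e-06, median -0.37), lipid uptake and droplets (0.000526, median -0.32), oxidation (0.00814), stellate cell (0.0117, median -0.19) and immediate early genes (0.0125) were lower. Log2 fold changes fell with gene length (Spearman -0.15). None of the lists passed with an estimated correlation (lowest adjusted p 0.21) or by fry, and no list had a member called over all genes. Adjusted over the list alone, 2 lipid uptake and droplet genes and 1 PPARA target fell. Without control A edgeR called 5 genes, and it called 1 without control B or E or knockout A, B or C. DESeq2 called 21 genes, and 1325 had an unadjusted p under 0.05.

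On high-fat diet the knockout raised 27 genes and lowered 11. Alb (ENSMUSG00000029368, chromosome 5, 90608756 to 90624461) rose from 25387 ± 3797 to 55481 ± 9216 CPM (1.13 ± 0.17, adjusted p 0.00792). Igfbp2, a circulating binding protein of insulin-like growth factors, rose from 798 ± 218 to 1726 ± 410 CPM, and Rdh16f2 from 94.2 ± 20.9 to 212 ± 26.7 (adjusted p 0.0125 each). Fam81a rose from 2.53 ± 1.02 to 9.02 ± 3.78 CPM and Nrg4, a hormone-like growth factor, from 5.08 ± 0.714 to 10.2 ± 2.76. The sulfate donor synthase Papss2 rose by 0.80 ± 0.17 and the B cell receptor gene Cd79a by 1.81 ± 0.38. Among genes that fell, the chaperone Hspa1a dropped from 3.74 ± 1.64 to 0.561 ± 0.229 CPM (adjusted p 0.0399) and its partner Bag3 from 59.9 ± 18.5 to 27.9 ± 5.25. Ugdh, which makes UDP-glucuronate, fell by 0.58 ± 0.11.

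By list, 2 of 24 periportal genes rose on high-fat diet (the lung and liver hydroxylase Cyp2f2, 0.60 ± 0.11, and the histidine-degrading enzyme Uroc1, 0.65 ± 0.14). Of 78 ribosomal protein genes 3 rose (Rps13, Rps6 and Rpl29), and of 20 immediate early genes 1 rose (Junb, 0.79 ± 0.16). No PPARA target, oxidation, stellate cell, fibrogenesis or endothelial gene passed. Camera with a preset correlation called 8 of 37 lists: ribosomal protein (adjusted p 5.13e-12), periportal (3.98e-08), glucose output (0.000424), immediate early (0.000453), lymphocyte and neutrophil (0.00178), glycolysis (0.00912) and oxidative phosphorylation (0.0453) as higher and the unfolded protein response (0.000915) as lower. Log2 fold changes fell with gene length here too (Spearman -0.11). None of the lists passed with an estimated correlation (lowest adjusted p 0.651) or by fry. Adjusted over the list alone, 15 ribosomal protein, 7 periportal and 6 immediate early genes rose. In place of 38 genes edgeR called 61, 6, 15, 8 or 20 without control A, B, C, D or E and 4 or 21 without knockout B or E. DESeq2 called 244, and removing a GC trend left 18.

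**Figure D2:**
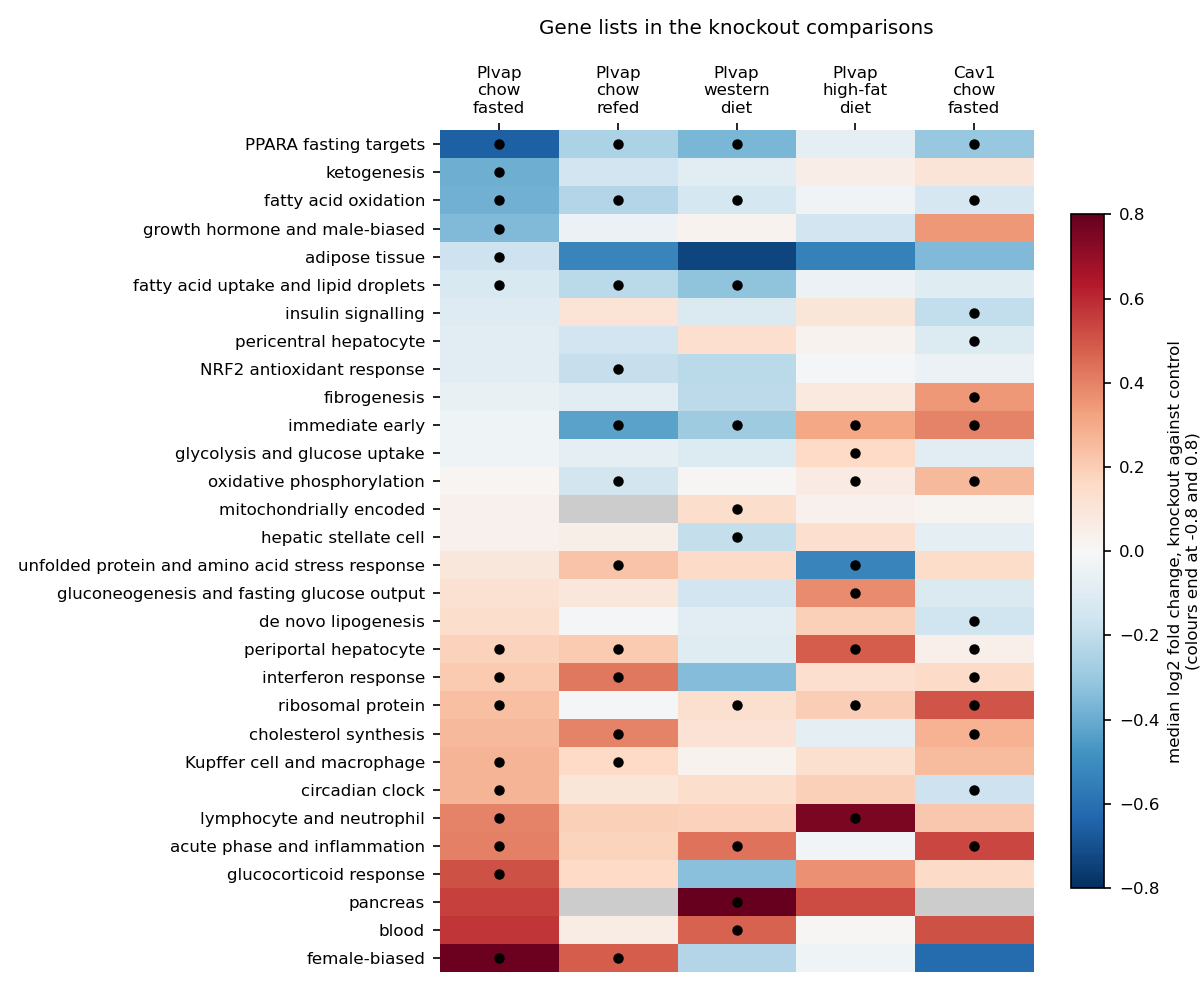
Median log2 fold change of each gene list (lists called in at least 1 knockout comparison) in the 4 Plvap experiments and the Cav1 experiment, with colours that end at -0.8 and 0.8, grey for lists not tested and a dot where camera with its preset correlation called the list. Not 1 of these calls passed with an estimated correlation in its comparison. The median of PPARA targets was -0.65 in chow fasted and -0.37 in western diet Plvap knockouts.

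The whole-body Cav1 knockout was compared with C57BL/6N wild types, so genotype and mouse stock differ together in every value that follows. Some genes were nearly on or off. Cebpe, a granulocyte transcription factor, had 18.8 ± 0.696 CPM in wild types and no count in the 4 knockouts, at least 342-fold lower against a floor of 3 counts over the group. Lrit2 was at least 134-fold lower, and its neighbour Lrit1 fell from 18.9 ± 2 to 0.44 ± 0.245 CPM, both being retinal membrane proteins. Myom2, a protein of muscle sarcomeres, had 22.4 ± 8.37 CPM in knockouts and no count in wild types (at least 466-fold higher). The protease inhibitor Serpina3c rose from 0.197 ± 0.119 to 61.3 ± 14.1 CPM (adjusted p 1.39e-07), and the protease Ctse from 0.471 ± 0.223 to 32.7 ± 15.3.

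Single members of several gene lists passed in the Cav1 knockouts, while no list passed with an estimated correlation (lowest adjusted p 0.76). Of 25 pericentral genes 4 fell and none rose, among them the cytochromes Cyp2c37 (-1.86 ± 0.17), Cyp2a5 (-1.19 ± 0.14) and Cyp2c50 (-1.11 ± 0.10). Of 24 periportal genes 5 rose and 1 fell. Apoa4, an apolipoprotein of lipid-rich particles, rose from 131 ± 28.8 to 808 ± 139 CPM (adjusted p 1.08e-05), and the glutaminase Gls2 fell by 0.45 ± 0.09. Of 27 cholesterol synthesis genes 2 rose (Sqle, 1.14 ± 0.23, and Mvk, 0.81 ± 0.16), and of 27 lipogenesis genes 2 fell (among them Aacs, -1.07 ± 0.20). Lipoprotein lipase, Lpl, rose from 11.3 ± 1.78 to 43.2 ± 20.1 CPM and Slc27a1 fell from 15.8 ± 6.09 to 8 ± 1.08. Of 35 fibrogenesis genes 2 rose, the matrix proteins Sparc (0.88 ± 0.09) and Lum (1.16 ± 0.19). Of 30 interferon genes 3 rose (Xaf1, Stat2 and Iigp1), of 30 acute phase genes 3 rose (Itih3, Fgg and Fgb), and of 25 cell cycle genes 2 rose and 2 fell. Of 10 caveolae genes Cav1 alone passed, and of 29 stellate cell genes 1 passed.

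EdgeR called 333 genes higher and 274 lower of 12978 between Cav1 knockouts and wild types. Camera with a preset correlation called 14 of 36 lists. Higher were ribosomal protein (adjusted p 1.88e-06), cholesterol synthesis (0.00772), immediate early (0.00772), oxidative phosphorylation (0.0117), acute phase (0.0192), fibrogenesis (0.0205), interferon (0.0376) and periportal genes (0.045). Lower were pericentral (0.0029), insulin signalling (0.00772), lipogenesis (0.0282), oxidation (0.0312), PPARA targets (0.0376) and clock genes (0.0376). All were lost with an estimated correlation (lowest adjusted p 0.76), and fry called 3. Adjusted over the list alone, 7 cholesterol synthesis and 7 acute phase genes rose, and 7 insulin signalling and 5 pericentral genes fell. Ribosomal protein genes took 2.20% of the counts of knockout B and 0.881% to 0.949% of those of the other 3 knockouts, and log2 fold changes fell with gene length (Spearman -0.29). Leaving out wild type A, B, C or D left 330, 402, 370 or 372 calls, and DESeq2 called 939.

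Western and high-fat diet were compared in control livers, where both diets stood in 1 table. Cholesterol synthesis genes differed together: 17 of 27 were lower on western diet and none higher. Sqle, a rate-limiting oxygenase of the sterol pathway, stood at 2.94 ± 0.916 CPM on western against 37.8 ± 14.6 on high-fat diet (-3.68 ± 0.54, adjusted p 0.00166). Idi1 was at 0.2 ± 0.159 against 5.25 ± 2.07 CPM. Scd1, which makes monounsaturated fatty acids, was higher on western diet (8466 ± 2555 against 435 ± 340 CPM, adjusted p 0.00416). So were the sterol exporters Abcg5 (1.43 ± 0.19) and Abcg8 (0.92 ± 0.13), the leptin receptor Lepr (44.2 ± 25.2 against 4.76 ± 1.08 CPM) and the drug-metabolising Cyp3a11 (3036 ± 1434 against 347 ± 208 CPM).

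Of 24 periportal genes 8 were higher on western diet, among them Apoa4 (1509 ± 670 against 253 ± 63.3 CPM) and Etnppl (169 ± 79.2 against 27.4 ± 14.7). Of 27 PPARA targets 5 were higher, among them Cyp4a14 (6873 ± 1702 against 1953 ± 952 CPM). The peroxisomal enzyme Ehhadh, which is on the oxidation list, was higher too (2462 ± 1184 against 741 ± 297 CPM). Of 23 genes of the unfolded protein response 5 were lower, among them the chaperones Calr (-1.16 ± 0.27) and Hsp90b1 (-1.02 ± 0.26). EdgeR called 149 genes higher and 134 lower on western diet, and 180 in all without western control D, 132 without high-fat control C and 142 without high-fat control D. Camera with a preset correlation called 20 of 37 lists, and 3 passed with an estimated correlation: cholesterol synthesis (adjusted p 7.56e-44, and 0.0283 with an estimated correlation), periportal genes (2.58e-13 and 0.0478) and pancreas genes (0.000148 and 0.0283), the last with 2 tested members. PPARA targets did not pass then (adjusted p 0.387), nor did the unfolded protein response (adjusted p 0.134). Adjusted over the list alone, 23 cholesterol synthesis genes were lower and 14 periportal genes higher.

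**Figure D3:**
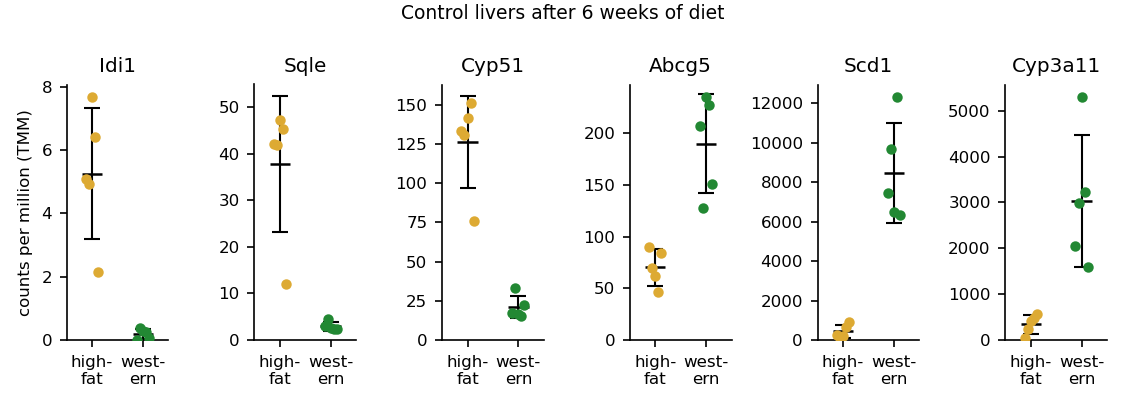
Normalised CPM of 6 genes that differed between high-fat and western diet in control livers, each gene on its own axis, with 1 point per liver, a line at each group mean and error bars of 1 SD (n = 5 each). Sqle was at 2.94 CPM on western and 37.8 CPM on high-fat diet, and Scd1 at 8466 and 435 CPM.

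Whether the Plvap knockout acts differently with feeding or diet was tested on the difference of effects itself. EdgeR called no gene for fasted against refed, chow against western, chow against high-fat or western against high-fat. At an unadjusted p under 0.05 there were 1192, 437, 1164 and 1546 genes, and DESeq2 called 5, 2, 12 and 56. Voom called 1 gene for fasted against refed and 20 for chow against high-fat, and edgeR with the replicate letter as a block called 3 and 4. Camera with a preset correlation called 3, 16, 11 and 9 lists in the same order and none with an estimated correlation, where the lowest adjusted p was 0.956, 0.104, 0.584 and 0.45. In simulated libraries of the same sizes a 2-fold difference of effects was recovered for 56.7% of genes between fasted and refed and for 46.3% between the diets. The simulated libraries held no structure shared between genes, so these shares may be too favourable for the real livers.

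Refed and fasted chow controls were sequenced in separate tables, so feeding and table cannot be told apart. Every refed library had 0 counts for mt-Co1, mt-Cytb, mt-Nd1 and 9 other mitochondrial genes, while mt-Co1 stood at 14079 ± 1468 CPM in fasted controls, and no biology is read from these. Mitochondrial genes and genes at 0 in a table (22 genes, called the genes at 0 below) were also left out in a further fit. In that fit no gene list passed camera with an estimated correlation (lowest adjusted p 0.94). The fatty acid synthase Fasn was at 246 ± 74.2 against 33.4 ± 5.79 CPM. Of 27 cholesterol synthesis genes 20 were higher and none lower, among them Mvd (56.1 ± 18.7 against 4.97 ± 2.1 CPM), and of 27 lipogenesis genes 15 were higher and 1 lower. Of 27 PPARA targets 14 were lower and 3 higher, among them Angptl4, an inhibitor of lipoprotein lipase (65.6 ± 36.5 against 341 ± 52.5 CPM). Of 31 oxidation genes 12 were lower and none higher, and the list was not called (camera adjusted p 0.0759 without the genes at 0). The glucose-releasing enzyme G6pc was at 124 ± 57.8 against 448 ± 135 CPM. Of 23 genes of the unfolded protein response 14 were higher, among them Creld2 (466 ± 94.6 against 41.3 ± 14.9 CPM) and Sdf2l1 (3.08 ± 0.48).

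EdgeR called 3436 genes higher and 3234 lower of 14234 between refed and fasted controls, so that shares of called members near those of all genes do not set a list apart. Of 25 Kupffer cell genes 12 were lower in refed controls, such as the lectin Clec4f (-1.15 ± 0.19). Of 36 fibrogenesis genes 14 were higher, such as the collagen chain Col4a2 (1.53 ± 0.20), and the list was not called (camera adjusted p 0.274 without the genes at 0). Of 11 caveolae genes 6 were higher and 1 lower, Cavin2 (-1.23 ± 0.19), and that list was not called either (adjusted p 0.347). With the genes at 0 left out, camera called 5 lists: cholesterol synthesis (adjusted p 2.61e-05) and lipogenesis (0.000267) and the unfolded protein response (0.00544) as higher, PPARA targets (0.00544) and Kupffer cell genes (0.0195) as lower. None of the 5 passed with an estimated correlation (adjusted p 0.94 each).

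Diet against chow in fasted controls also spans separate tables. The 5 western controls are the same livers as in the comparison with high-fat diet. In them 18 of 27 cholesterol synthesis genes were lower than on chow and none higher (Sqle 2.98 ± 0.933 against 31.2 ± 17.9 CPM, adjusted p 0.000405). Of 30 interferon genes 16 were higher, among them Bst2 (279 ± 133 against 146 ± 15.9 CPM) and Mx1 (3.23 ± 1.9 against 1.27 ± 0.396). Lipoprotein lipase was higher (94.8 ± 60.6 against 29.3 ± 3.87 CPM) and 4 of 32 endothelial genes lower, among them Aqp1 (-0.55 ± 0.12). EdgeR called 160 genes higher and 98 lower, and 149 in all without chow control D. Cholesterol synthesis passed camera with the preset (adjusted p 6.48e-48) and with an estimated correlation (0.0119), while interferon genes passed with the preset (3.3e-21) and not with an estimated correlation (adjusted p 0.102). In all 15 lists passed with the preset and 1 with an estimated correlation. Among the other lists that passed with the preset alone were ribosomal protein genes as lower (adjusted p 9.8e-08) and cell cycle (0.00204), adipose tissue (0.0048) and lymphocyte and neutrophil genes (0.0168) as higher.

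On high-fat diet against chow, genes of drug metabolism and of the periportal zone were lower. The high-fat controls are the same livers as in the comparison with western diet, so the 2 comparisons are not independent. Of 27 xenobiotic genes 10 were lower and none higher, among them Cyp3a11 (352 ± 211 against 4927 ± 1218 CPM, adjusted p 1.73e-05) and the glucuronosyltransferase Ugt1a9 (1.87 ± 0.664 against 16.5 ± 3.51). Of 24 periportal genes 13 were lower and none higher, among them the urea cycle enzyme Asl (295 ± 106 against 981 ± 221 CPM). Of 17 antioxidant genes 7 were lower and 1 higher, among them Ephx1 (-0.93 ± 0.17). Of 23 genes of the unfolded protein response 12 were higher and 2 lower, and of 17 genes of glucose output 7 were lower. The steroid dehydrogenase Hsd3b5 was higher (499 ± 34.5 against 77.5 ± 47.8 CPM), and the clock genes Per2 (1.87 ± 0.27) and Arntl (-1.54 ± 0.30) moved apart. EdgeR called 599 genes higher and 605 lower, and 668 or 731 in all without high-fat control C or D. Camera called 18 lists with the preset and 3 with an estimated correlation: xenobiotic (adjusted p 2.77e-08 and 0.0196), periportal (5.26e-12 and 0.0344) and antioxidant genes (3.66e-05 and 0.0496). The unfolded protein response did not pass then (adjusted p 0.411), nor did glucose output (adjusted p 0.299). Of 30 interferon genes 7 were higher and none lower on high-fat diet too, over the same 2 tables (camera adjusted p 2.91e-09, and 0.408 with an estimated correlation). Xenobiotic and antioxidant genes were lower on western diet against chow as well (camera adjusted p 0.0149 and 0.000334 without the genes at 0). With an estimated correlation they did not pass (adjusted p 0.354 and 0.0822). Periportal genes were not called there (camera adjusted p 0.851). Diet and table cannot be told apart in either comparison.

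The knockout effects were compared between experiments, which share no control livers. Across genes, which are not independent replicates, log2 fold changes correlated with r of 0.436 between chow fasted and western, 0.345 between chow fasted and high-fat and 0.31 between chow fasted and refed. Against 100 draws with knockout labels permuted within each experiment, the adjusted permutation p was 0.066 for each, and no pair of the 10 passed. With 100 draws the smallest possible p is 0.0099, so 1 pair by itself could not pass after adjustment over 10 pairs. For chow fasted, 0 draws were as large with high-fat, 1 with western and 1 with refed. By Spearman correlation these numbers were 4, 1 and 10. Some overlaps of called genes passed and others did not. Fisher's exact test treats genes as independent, so its p values do not measure agreement between livers. Chow fasted and high-fat knockouts shared 7 raised genes (0.281 by chance, Fisher exact adjusted p 1.6e-07), namely Alb, Fam81a, Hgfac, Plbd2, Rdh16f2, Tsc22d4 and Uroc1. Of lowered genes this pair shared Plvap alone (Fisher exact adjusted p 0.18). Chow fasted Plvap and Cav1 knockouts shared 14 raised genes (3.08 by chance, Fisher exact adjusted p 2.43e-05), Alb and Tff3 among them, and 8 lowered genes (2.96 by chance, Fisher exact adjusted p 0.0225). For this pair r was 0.159 across genes, with an adjusted permutation p of 0.368. High-fat Plvap and Cav1 knockouts shared 3 raised genes, Alb among them (0.575 by chance, Fisher exact adjusted p 0.0347), and 0 lowered ones (Fisher exact adjusted p 1). Chow fasted and refed Plvap knockouts shared the lowered genes Fitm1 and Plvap (Fisher exact adjusted p 0.00189). Plvap was targeted in both, so its sharing was fixed by the design, and that p counts it. Fitm1 is the only other shared gene. The other pairs of Plvap experiments shared Rdh16f2, Plvap or no gene. Refed Plvap and Cav1 knockouts shared 1 lowered gene (Fisher exact adjusted p 0.105), and western Plvap and Cav1 knockouts shared 0 either way (Fisher exact adjusted p 1). The shared genes were named after these overlaps were seen.

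The mean Plvap knockout effect over the 4 experiments was added after the data were seen, and so were the genes named for it. It called 445 genes higher and 349 lower of 14234, of which 595 were called in no single experiment. Rdh16f2 rose by 1.15 ± 0.09 (adjusted p 1.57e-11) and Alb by 0.88 ± 0.07. The secreted proteins Hgfac (0.64 ± 0.07), Afm (0.58 ± 0.07), the complement regulator Cfi (0.50 ± 0.07) and Ahsg (0.44 ± 0.06) rose, and so did Tff3 (2.62 ± 0.34). Cidec fell by 1.73 ± 0.21, Cyp4a12b by 1.19 ± 0.12, the aldehyde dehydrogenase Aldh3a2 by 1.00 ± 0.15 and the ornithine aminotransferase Oat by 0.58 ± 0.10. Of 39 lipid uptake and droplet genes 10 fell and 3 rose (camera adjusted p 3.91e-05, and 0.048 with an estimated correlation). Slc27a1, a neighbour of Plvap, is among the 10 that fell. Adipose tissue genes fell beside the lipid list: 4 of 9 fell and none rose (Cidec, which is on both lists, Pparg, Plin1 and Adipoq), with a median of -1.38 (camera adjusted p 0.00135, and 0.214 with an estimated correlation). Of 31 oxidation genes 12 fell and 1 rose (2e-11, and adjusted p 0.214 with an estimated correlation), and of 27 PPARA targets 9 fell and none rose (5.82e-13, and adjusted p 0.116 with an estimated correlation). Fabp2, Plin2, Mgll and Cidec fell on both the PPARA and the lipid uptake and droplet list, so these counts are not independent. Of 79 ribosomal protein genes 10 rose and none fell (5.52e-09, and adjusted p 0.685 with an estimated correlation). Lymphocyte and neutrophil genes had a median of 0.38 with 2 of 24 higher (2.05e-05, and 0.214), and of 25 Kupffer cell genes 1 rose (0.00317, and 0.711). None of 36 fibrogenesis genes passed, and of 29 stellate cell genes 2 rose and 1 fell.

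Passenger sequence around a targeted locus was the last question. Within 5 Mb of Plvap none of 111 tested neighbours was called in chow fasted knockouts and 1 of 115 in refed ones, Slc27a1 (Fisher exact p 0.0173, which rests on 2 called genes, 1 of them elsewhere). On western and high-fat diet 0 of 114 were called in each (Fisher exact p 1). Near Lrat, whose promoter drives the Cre, 1 of 39 neighbours was called in chow fasted knockouts, Fga (Fisher exact p 0.589), and 0 of 42 in refed, 0 of 43 in western and 0 of 43 in high-fat ones (Fisher exact p 1 each). Near Cav1, 1 of 20 was called in Cav1 knockouts (Fisher exact p 0.616). These counts cover single experiments. For the mean Plvap effect, Slc27a1 near Plvap was called as lower and Rbm46, 0.0161 Mb from Lrat, as higher (adjusted p 2.13e-06). Fgg, Fga and Fgb near Lrat were not called. Rbm46 was not tested in chow fasted or refed knockouts, so the counts there leave it out. Where the Cre lies in the genome was not tested, so counts near Lrat cannot decide whether sequence came with it.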

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

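The tests of strain variants, of sequence carried with the Cre driver and of a lower hepatocyte share were chosen after the result was seen, and so were the mean effect over the 4 Plvap experiments and the counts near Plvap in the Cav1 comparison. Values that stand apart within their group were found with Dixon's test, which chance passes in about 1 of 20 groups.

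Fatty acid oxidation genes and PPARA targets were lower in chow fasted Plvap knockouts, with a median log2 fold change of -0.43 over the 58 members of both lists. Gene length as the whole cause is argued against, since the median was -0.42 with the length trend removed, a correction that moved all genes by a median of 0.0366. GC content is argued against less strongly, as the median was -0.43 after a correction that moved genes by a median of only 0.0126. A lower share of hepatocytes as the whole cause is argued against by the other 49 members of the zonation lists, whose median was 0.054. Its SE of 0.072 treats these genes as independent. Whether the share itself changed is not settled. Kupffer cell and lymphocyte and neutrophil genes were called as higher by camera with its preset correlation, and not with an estimated one. What stays open is an effect of the knockout, which may be stated only as a hypothesis because adjusted p was 0.242 for both lists with an estimated correlation, and a structure among the controls. Of these A, B and C (-23.1, -17.4 and -22.0 on the first principal component, 39.2% of the variance) lie on the far side of D, E and F (-0.014, -0.40 and 5.09) from most knockouts. Without control A, B or C there were 160, 134 or 101 calls in place of 289. That fall is not particular to them, as leaving out knockout A, B, D or E lowered the count too.

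Called genes of the Cav1 comparison lie side by side on chromosomes other than that of Cav1. The count of adjacent called pairs was 3.01 times that of permuted calls (SE 0.332, permutation p 1e-04, the smallest that 10000 permutations can give), and it was 2.60 without neighbours that share the start of their symbol, which argues against reads shared between paralogs as the whole cause. The bound set against strain variants was a ratio at or below that of the chow fasted Plvap comparison, 3.46 (SE 0.755), and it was crossed. The reading of that bound was changed after its value was seen, because the 2 ratios differ by less than their spread, and the reason why called genes lie side by side in the Plvap comparison was not tested. Wild types and Cav1 knockouts come from different stocks, so strain and knockout cannot be told apart, and runs such as 19 called of 102 tested genes on chromosome 8 (69246581 to 73011229) and 7 called of 15 tested on chromosome 14 (34032684 to 36795700) stay open.

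Rbm46 (ENSMUSG00000033882) lies 0.0161 Mb from Lrat, whose promoter drives the Cre, and was higher in Plvap knockouts, with a mean log2 fold change of 1.87 ± 0.23. Chance at low counts is argued against by its adjusted p of 2.13e-06, although it was near the floor in each Plvap experiment. It stood at 0.832 against 0.193 CPM in chow fasted and 0.618 against 0.191 in refed livers. On western diet it stood at 0.790 against 0.176 CPM and on high-fat diet at 0.619 against 0.202. The refed groups overlapped (exact permutation p 0.0571). Rbm46 passed in no single experiment where it was tested. Its mean was 431.5%, 323%, 450% and 307% of control in chow fasted, refed, western and high-fat knockouts and 73.5% of wild type in the Cav1 knockouts. The gene was chosen for this rise and every Plvap knockout carries the Cre, so these values cannot decide between sequence carried with the Cre driver and loss of Plvap. The neighbours Fgg (0.14), Fga (0.26), Fgb (0.24), Plrg1 (-0.10) and Lrat (0.02) were not called for the mean effect, while Fga was called in chow fasted knockouts (0.57 ± 0.14, adjusted p 0.044).

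Other splits of the same livers were counted beside the real one. Where more than 100 splits exist, 100 were drawn, so a split that was not drawn may call more genes. For chow fasted Plvap knockouts chance is unlikely for the count of genes, with 289 against at most 193 in the other splits drawn (1 of 100 splits). The same holds for high-fat knockouts (38 against 6), Cav1 knockouts (607 against 3, 1 of 35 splits), western against high-fat diet (283 against 3), refed against fasted (6670 against 3875), western diet against chow (258 against 183), high-fat diet against chow (1204 against 10) and the mean effect (794 against 138). Chance cannot be excluded for refed knockouts (3 against 5, 2 of 35 splits), and among the 8 splits that part all 4 pairs of replicate letters the highest other was 0, while splits that kept pairs together reached 5. It cannot be excluded for western diet knockouts either (2 against 10, 5 of 100 splits).

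For the differences of effects the real counts were 0, so all 100 of 100 splits gave as many by construction, which decides nothing about chance. Between fasted and refed 89 of the 99 other splits called 0 as well and the highest called 230, and between western and high-fat diet these numbers were 94 and 17. Why single splits made so many calls, for example through a structure of the samples, was not tested. The highest other was 6 for chow against western and 2 for chow against high-fat diet. The number of gene lists called by camera with its preset correlation does not exclude chance in any comparison where it was counted. It was 15 against 19 in chow fasted knockouts (19 of 100 splits), 12 against 16 in refed (18 of 35), 14 against 23 in Cav1 (21 of 35), 10 against 19 in western (70 of 100), 8 against 19 in high-fat knockouts (72 of 100) and 16 against 20 for the mean effect (9 of 100).

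Of 38 measures of libraries 7 stood apart from their group. Albumin took 6.86% of the counts of chow fasted knockout B (others 5.07% to 5.37%) and 7.17% of high-fat knockout E (4.78% to 5.45%). Mitochondrial genes took 4.81% of wild type A (4.18% to 4.26%) and 5.76% of western knockout B (4.88% to 4.91%). Ribosomal protein genes took 0.927% of wild type B (0.846% to 0.851%) and 2.20% of Cav1 knockout B (0.881% to 0.949%). Cav1 knockout C had 10902551 counts in all (others 14805312 to 15298559).

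Of 354 values of genes and groups tested in the same way 27 stood apart, and those of genes named in the text follow in CPM. In chow fasted livers they were Hamp2 5.33 in control B, Decr1 433.1 in control D, Cyp3a44 1.11 in control A, and Acot2 7.13 and Clstn3 14.3 in knockout C. In the Cav1 experiment Ctse was 0.14 in wild type A and 55.5 in knockout D. On western diet Arhgap26 was 31.3 in knockout B. On high-fat diet Alb was 71575 in knockout E, Cyp2f2 660 in control E and Rps6 70.7 in control D. In the comparison of diets Sqle was 11.9 and Cyp51 76.0 in high-fat control E, and the value of Rps6 in high-fat control D stood apart there too.

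Gene lists for which the Plvap effect differed between conditions by camera with its preset correlation are given with their median difference in log2 fold change. None passed with an estimated correlation. For western minus high-fat diet (adjusted p 0.45 to 0.776 with the estimated correlation) they were cholesterol synthesis 0.26, glucose output -0.50, glycolysis -0.26, lipid uptake and droplets -0.18, stellate cell -0.36, mesothelium 1.09, periportal -0.59, unfolded protein response 0.71 and immediate early -0.62. For fasted minus refed (adjusted p 0.956) they were male-biased -0.37, oxidative phosphorylation 0.17 and ribosomal protein 0.25.

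For chow fasted minus western diet (adjusted p 0.104 to 0.83 with the estimated correlation) they were oxidation -0.21, PPARA targets -0.19, ketogenesis -0.28, glucose output 0.20, stellate cell 0.20, endothelium -0.093, Kupffer cell 0.28, cholangiocyte -0.20, mesothelium -0.56, pericentral -0.14, periportal 0.31, interferon 0.53, glucocorticoid 0.77, male-biased -0.47, female-biased 0.94 and ribosomal protein 0.11. For chow fasted minus high-fat diet (adjusted p 0.584 to 0.791) they were oxidation -0.37, PPARA targets -0.45, ketogenesis -0.37, cholesterol synthesis 0.25, glycolysis -0.11, Kupffer cell 0.16, periportal -0.28, unfolded protein response 0.54, acute phase 0.47, male-biased -0.31 and immediate early -0.45.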

How the results depend on the processing

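Corrections for gene length and GC content, fits without mitochondrial genes and genes at 0 in a table, the mean effect over the 4 Plvap experiments and the counts near Plvap in the Cav1 comparison were added after the data were seen. The cause of the changes below was not tested.

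DESeq2 called 713 genes in chow fasted, 59 in refed, 21 in western and 244 in high-fat Plvap knockouts, 939 in Cav1 knockouts, 591 between western and high-fat diet and, rounded, 4.0e+02 between western diet and chow. Without a filter edgeR called 861, 131, 10, 99 and 1279 in the first 5 of these, and 731 between high-fat diet and chow. Voom with quality weights called 490, 10, 15 and 110 in the 4 Plvap experiments, 490 between western and high-fat diet and 2381 between high-fat diet and chow. With the replicate letter as a block edgeR called 713 in chow fasted, 30 in refed and 1 in western knockouts, and 166 between western diet and chow. In refed knockouts the block called 44 genes with a length correction and 18 with a GC correction. On western diet the compared groups alone gave 1 gene, and on high-fat diet the GC correction gave 18.

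For the differences of effects, where edgeR called 0 genes, DESeq2 called 5 between fasted and refed, 2 between chow and western, 12 between chow and high-fat and 56 between western and high-fat diet. Between fasted and refed, edgeR called 4 without a filter and 3 with the block, and voom 1. Between western and high-fat diet edgeR called 10 without a filter. Between chow and high-fat diet voom called 20, and edgeR with the block 4. At an unadjusted p under 0.05 edgeR had 1192, 437, 1164 and 1546 genes in the order of the first sentence.

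Over all comparisons camera with its preset correlation made 157 calls of gene lists, with an estimated correlation it made 8, and fry, counted by itself, made 49. Of these 8, 1 was for refed against fasted controls, and it was lost with mitochondrial genes and genes at 0 in a table left out. With an estimated correlation 0 lists passed in chow fasted, refed, western and high-fat Plvap knockouts and in Cav1 knockouts. Fry called 0 in refed, western and high-fat and 3 in Cav1 knockouts, where a length correction left 9 camera calls. The correlation of effects between refed Plvap and Cav1 knockouts was 0.0231 by Pearson and -0.0527 by Spearman.

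Leaving out 1 library at a time moved the counts. Chow fasted knockouts had 90 to 550 calls against 289: 160, 134 and 101 without control A, B and C, and 139, 97, 550, 133 and 90 without knockout A, B, C, D and E. Refed knockouts had 0 to 4 against 3: 1 without control B and 0 without control D or knockout A or B. Plvap was no longer called there without control D (adjusted p 0.0871) or knockout A (0.122), B (0.171), C (0.0615) or D (0.0833). Western knockouts had 1 to 5 against 2: 5 without control A and 1 without control B or E or knockout A, B or C. High-fat knockouts had 4 to 61 against 38: 61, 6, 15, 8 and 20 without control A, B, C, D and E, and 4 and 21 without knockout B and E. Cav1 knockouts had 330 to 671 against 607: 330, 402, 370 and 372 without wild type A, B, C and D.

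Western against high-fat diet had 132 to 307 calls against 283: 180 without western control D and 132 and 142 without high-fat control C and D. The difference between these diets had 0 to 1, with 1 without western control B or high-fat knockout C. That between fasted and refed had 0 to 17: 3 without chow control F, 4 without refed control D or knockout A, and 17 without refed knockout C. That between chow and western had 0 to 1, with 1 without chow control A. That between chow and high-fat had 0 to 12: 12 without chow knockout C and 1 without chow knockout B or high-fat control E. Refed against fasted had 5905 to 6625 calls. Western diet against chow had 149 to 271 against 258, with 149 without chow control D. High-fat diet against chow had 668 to 1341 against 1204, with 668 and 731 without high-fat control C and D. The mean effect had 655 to 984 calls. Plvap lay between -2.42 and -2.25 in chow fasted, -2.65 and -2.28 in refed, -2.51 and -2.27 in western and -2.20 and -1.87 in high-fat knockouts, and Cav1 between -3.12 and -2.41 in Cav1 knockouts.

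Of the values of named genes, 3 were no longer past the test by DESeq2 and 5 newly past it. With size factors these numbers were 2 and 0, without a filter 51 and 3, with the strict filter 3 and 0, by voom 25 and 2, with the block 56 and 2, with the length correction 15 and 0, with the GC correction 27 and 0, with the compared groups alone 13 and 0 (8 of the 13 in high-fat knockouts), and with 1 library left out 654 and 3. The remaining 3598 values with 1 library left out stayed on their side.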

Other observations

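All genes and lists named here were chosen after the data were seen. In the mean Plvap effect over the 4 experiments 3 of 17 antioxidant genes fell, Aox1, Prdx1 and Ugdh (camera adjusted p 0.00744, and 0.214 with an estimated correlation). The fall of adipose tissue genes leaves open whether fat tissue taken with the liver differed between the groups. Of 24 periportal genes 5 rose and 1 fell (4.52e-05, and 0.214), with Gls2 among those that rose and Apoa4 as the one that fell, while in Cav1 knockouts Apoa4 rose and Gls2 fell. No caveolae gene of 11 passed. Gldn (gliomedin, which clusters ion channels at the nodes of nerve fibres) rose by 2.53 ± 0.36, and Npnt, an integrin ligand of basement membranes, fell by 2.09 ± 0.32. The heparin cofactor gene Serpind1 rose by 0.37 ± 0.05.

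In refed livers the replicate letter as a block brought further genes past the test by edgeR. Hsd17b6, a steroid and retinol dehydrogenase, rose by 1.92 (adjusted p 0.00043). Rdh16f2 rose by 1.01 (adjusted p 0.00882), and Cyp4a12a fell by 0.92 (adjusted p 0.00999). The lipid droplet coat gene Plin2 fell by 0.79 (adjusted p 0.0359), and the peroxisomal thiolase Acaa1b by 0.82 (adjusted p 0.027). The activin subunit Inhbb fell by 1.84 (adjusted p 0.0181), and Clstn3 by 1.66 (adjusted p 0.027). Lists of pericentral (adjusted p 0.0356, lower), clock (0.0141, higher) and ribosomal protein genes (0.00666, lower) were called by camera with its preset correlation with the block and not without it. With an estimated correlation, added after the data were seen, each of the 3 had adjusted p 0.699 with the block.

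Called genes lay close to Plvap in the Cav1 comparison, where Plvap is not targeted: 19 of 112 neighbours within 5 Mb were called (Fisher exact p 9.65e-07). They are the called genes of the chromosome 8 run given above (69246581 to 73011229), so this is not a further observation. Slc27a1 is one of them, and it fell both there and in refed Plvap knockouts. Whether the region differs between the mouse stocks was not tested by genotype.

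Chow fasted controls A, B and C stood apart from controls D, E and F on the first principal component. The labels give no batch that parts them.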
